A study of Mus musculus with 27 samples.

How the data were processed

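Left ventricles of FVB mice, WT or caPI3Kalpha, were taken 7 days after a sham operation or TAC. The series holds 27 libraries: 16 of small RNA and 11 of messenger RNA. Titles give each animal a number, and 11 animals have both kinds of library while 5 have a small RNA library alone. All table columns were matched to a sample by group and number, and 0 columns matched none. For 1 mRNA library, WT sham 15, the title and the source name give different animal numbers, and the title, which matches the column name, was used.

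The mRNA table holds RPKM, computed by the authors from single-end reads of poly-A selected libraries per the labels, printed to 1 decimal. The deposited table lists genes whose highest RPKM is 3 or more. Low values at 1 decimal show no steps of single reads, so the depth of the mRNA libraries is unknown. The miRNA table holds raw read counts on miRBase v.16 miRNAs, as deposited by the authors per the file headers. CASAVA 1.6, Bowtie, Partek 6.5 and mm9 are named in the submitters' processing notes with no role given, and mapping settings are not given in the sources used here.

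Of 9251 mRNA lines 261 were blank, 1 held an error mark and 2 were repeats, which left 8987 genes. The RPKM of the listed genes summed to between 202916.4 and 212396.3 per library. Of 421 miRNAs 8 had no read. Counted miRNA reads were 6205989, 4745609, 3114229 and 4158008 in WT sham 6, 7, 13 and 15, 7301488, 3635462, 5279126, 3419653 and 4066443 in WT TAC 1, 2, 17, 19 and 20, 6017503, 6756683 and 4541403 in caPI3Kalpha sham 5, 8 and 14, and 7676588, 4682160, 6422557 and 5115234 in caPI3Kalpha TAC 8, 9, 11 and 211. Variation between hearts of a group far exceeded counting error: the lowest chi-square per degree of freedom between 2 libraries of a group was 46.9.

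Because the table holds RPKM, mRNA was tested with limma 3.58.1 (lmFit and eBayes with trend, not robust) on log2(RPKM + 0.5) in 1 model of 4 groups. A filter at a mean of 1 RPKM removed 0 genes. MiRNA counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr), which tested 262 miRNAs. R was version 4.3.3. TMM factors ran from 0.867 to 0.953 in WT sham, 1.08 to 1.18 in WT TAC, 0.842 to 0.912 in caPI3Kalpha sham and 0.894 to 1.10 in caPI3Kalpha TAC. The 5 comparisons were WT TAC with WT sham, caPI3Kalpha sham with WT sham, caPI3Kalpha TAC with caPI3Kalpha sham, the interaction of genotype and operation, and caPI3Kalpha TAC with WT TAC. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 and no fold limit. Groups, tests, lists and alternatives, other than those named below as added later, were fixed before the data were examined.

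Lists of genes (26) and of miRNAs (8) were written down in advance from known heart biology and tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the data. Members past the threshold were counted over all genes and adjusted over the list alone. For 1 member of the lists the values are not reported here. List scores are means of log2 values per library. Genes were named by a rule set in advance. It takes the 6 largest rises and 6 largest falls past the threshold with groups that do not overlap, up to 4 members of each described list with the smallest p, a fixed set of heart genes and miRNAs whatever their p, and the members of the miRNA and mRNA pairs. The blood and atrial genes, Meg3 and the low-count miRNAs were chosen after their values were seen. Correlations used 100000 permutations, with exact tests where n was 6. Where a group had no read, a fold is a lower bound against 3 counts over the group, and intervals for low counts are at 95% and cover counting error alone.

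The library sets were found in the data. For mRNA they are the sign of the first principal component, which held 52.0% of the variance, and for miRNA the presence of a space in the column name. The sets are not given by the labels. WT sham 7 is in the second mRNA set and the first miRNA set.

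Alternatives were other pseudocounts, quantile normalization, centring on library medians, no filter, DESeq2 1.42.0, fits of the 2 compared groups alone, estimated correlations and leaving out each library in turn. A set term, fits within each set and library totals without TMM were added after the data were seen. Match of miRNA seeds to 3' untranslated regions, GC content and gene length were left out, since no reference for the build used came with the series.

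The tests were run on simulated data in which 100 genes or 20 miRNAs were changed at each of 2 sizes. At 2-fold and 4-fold the planned mRNA test recovered 74 and 95 genes for WT TAC with WT sham, 60 and 94 for caPI3Kalpha sham with WT sham, 47 and 92 for caPI3Kalpha TAC with sham, 28 and 75 for the interaction and 64 and 95 for the 2 TAC groups. For miRNAs it recovered 12 and 19, 12 and 16, 6 and 18, 7 and 15, and 14 and 18 of 20 in the same order. Between 0 and 10 unchanged genes were called. A list raised in the simulation was called in all 5 comparisons, and 0 of the other 20 lists were. Apart from the library set differences, noise was drawn independently for each gene. The simulation therefore could not show false list calls that come from correlation between genes.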

Results

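The series measured microRNAs and messenger RNAs in the left ventricle of mice that were wild type (WT) or carried caPI3Kalpha, a constitutively active form of the alpha catalytic subunit of phosphoinositide 3-kinase, an enzyme known for its part in physiological heart growth. Each mouse had a sham operation or transverse aortic constriction (TAC), which narrows the aorta and loads the ventricle with pressure, and was studied 7 days later. Small RNA was sequenced from 16 hearts: 4 WT sham, 5 WT TAC, 3 caPI3Kalpha sham and 4 caPI3Kalpha TAC. Messenger RNA was sequenced from 11 of these hearts: 4, 3, 2 and 2 in the same order. The miRNA libraries held between 3114229 and 7676588 counted reads. The mRNA values were RPKM and their depth is unknown. Changes below are log2 fold changes with their standard errors (SE), from limma for mRNA and edgeR for miRNA, and means carry the standard deviation (SD) between hearts.

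The libraries were divided into 2 sets that the labels do not give, by the sign of the first principal component for mRNA and by the form of the column name for miRNA. In the mRNA data 1 set held WT sham 6, WT TAC 1 and all 4 caPI3Kalpha libraries, and the other held WT sham 7, 13 and 15 and WT TAC 17 and 19. Spearman's rho between mRNA libraries ran from 0.931 to 0.989 within a set and from 0.848 to 0.913 across sets, and 4853 of 8987 genes differed between the sets; as these sets were defined from the same values, the numbers give the size of the split and do not test it. In the miRNA data, where each set held 8 libraries and hearts of all 4 groups, 133 of 262 miRNAs differed. Values with a term for the set in the model, added after the data were seen, are given where they move a result. The mRNA set with WT sham 6, called the first set below, holds 1 WT sham and 1 WT TAC library. Tests of WT groups within it take their spread from the caPI3Kalpha libraries, so passing or not passing there says little.

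The first comparison asks what pressure load does to the WT ventricle. Of genes known from the stressed heart, Nppa, which encodes atrial natriuretic peptide, went from 79.2 ± 26.7 RPKM (SD, n = 4) in WT sham to 879.6 ± 304 (SD, n = 3) in WT TAC, a log2 change of 3.47 (SE 0.30, adjusted p = 7.00e-05). Acta1, the skeletal alpha-actin gene expressed in the fetal heart, rose 9.44-fold (log2 3.24, SE 0.56; 3.89 without WT sham 6 and 1.40 within the first set) and Nppb, which encodes B-type natriuretic peptide, 4.77-fold (log2 2.25, SE 0.39). Postn, which encodes the matrix protein periostin, rose from 10.8 ± 1.69 to 171 ± 29.1 RPKM (log2 3.92, SE 0.15, adjusted p = 2.75e-07). Fatty acid oxidation genes fell, among them Acaa2, a thiolase of mitochondrial beta-oxidation, by 0.86 on the log2 scale (SE 0.10, adjusted p = 0.000483).

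Of 39 measured extracellular matrix genes, 38 rose over all genes tested and 39 adjusted over the list alone, with a median log2 change of 2.05 (camera, adjusted p = 9.75e-31). Col1a1, a chain of type I collagen, rose 8.00-fold (log2 3.00, SE 0.46; 2.39 without WT TAC 1), and Col8a1, Col5a2 and Bgn, which encodes biglycan, rose by 2.56, 2.53 and 2.05 on the log2 scale. Spp1, which encodes osteopontin, rose 11.8-fold, Timp1, an inhibitor of matrix metalloproteinases, 9.58-fold, and Ccl8, a chemokine, 9.24-fold. The first 2 are near the floor in sham: with a pseudocount of 0.1 Spp1 rose 32.8-fold and Timp1 14.5-fold, and with 1 Spp1 rose 7.14-fold; within the first set Spp1 rose 27.2-fold. Markers of other cell types moved with these genes: 10 of 11 macrophage markers rose, 10 adjusted over the list alone, with a median of 1.13 (adjusted p = 0.0691 with an estimated correlation), for example Ctss at 1.57 and Csf1r, the receptor for macrophage colony-stimulating factor, at 1.04. Of 9 fibroblast markers 4 rose, 8 adjusted over the list alone, among them Lum (1.52) and Tcf21 (1.13; 0.42 within the first set). Of 8 cell cycle genes 7 rose, 8 adjusted over the list alone, including Mki67 (2.10, SE 0.34) and Ccna2 (1.62), which mark dividing cells.

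Among 12 hypertrophic marker genes 8 rose, 10 adjusted over the list alone, and 4 did not pass over all genes. Ankrd1, a stress-responsive sarcomere protein, rose 3.92-fold and Xirp2 4.61-fold. Myh7, the slow myosin heavy chain whose rise often marks hypertrophy in mice, stood at 0.11 (SE 0.23, limma adjusted p = 0.788). Centred on library medians it stood at -0.08. Mapping settings are not given, so how reads were divided between Myh7 and the other myosin heavy chain, Myh6, is unknown. The value does not exclude a rise of Myh7, and miR-208b, encoded within Myh7, rose in WT TAC, as given below. Myh6, the adult mouse myosin heavy chain, fell by 0.68 and Atp2a2, the calcium pump of the sarcoplasmic reticulum, by 0.49 on the log2 scale. Over the 17 genes of adult contraction and calcium handling 3 fell and 1, Ttn, rose; adjusted over the list alone 5 fell and 1 rose. With quantile normalization 1 fell and 1 rose, and centred on library medians 7 fell and 0 rose. Of 24 ion channel genes 2 fell, Kcnv2 (-1.09) and Cacnb2 (-0.53), and 1 rose; adjusted over the list alone 2 fell and 0 rose, with a median of -0.22 (adjusted p = 0.0126 with an estimated correlation). With quantile normalization 3 fell and centred on library medians 7, and 0 rose in either.

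Of 28 genes of fatty acid uptake and oxidation 18 fell, 25 adjusted over the list alone, with a median of -0.60: Hadha, a subunit of the trifunctional protein, changed by -0.61 and Ucp3, a mitochondrial carrier, by -1.22. Of 14 citric acid cycle genes 9 fell (13 adjusted over the list alone), for example Cs, the citrate synthase gene (-0.41), and of 40 respiratory chain genes 12 fell (22 adjusted over the list alone), for example Cox7a1 (-0.61). The falls in these 2 lists numbered 3 and 6 with quantile normalization and 12 and 26 centred on library medians. Glycolysis genes were mixed, with 4 of 22 down and 1 up, and the same counts adjusted over the list alone; Pfkp rose by 0.82 and Eno3 fell by 0.61 (adjusted p = 0.256 with an estimated correlation). Other falls were those of Retnla (-2.13; -2.77 with a pseudocount of 0.1), Pfkfb1 (-1.93), Timp4 (-1.68), Penk, which encodes proenkephalin (-1.62), Mylk4 (-1.47) and Efnb3 (-1.38); within the first set alone Retnla, Penk and Timp4 stood at -0.81, -0.77 and -0.53 and did not pass. Of 14 genes of the unfolded protein and oxidative stress responses 7 rose, 7 adjusted over the list alone (adjusted p = 0.207 with an estimated correlation), Hmox1 among them (1.21); with quantile normalization 3 rose, and centred on library medians 3 rose and 1 fell.

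In all, 1481 of 8987 genes passed an adjusted p of 0.05, with 1225 higher and 256 lower in WT TAC. Rises of at least 2-fold numbered 308 and falls 22. The median log2 change of all genes was 0.17. Centred on each library's median, 561 genes were higher and 610 lower, and with quantile normalization 486 and 439, so that the excess of rises depends on the scaling. Without WT sham 7 the count was 883 and without WT TAC 17 it was 729. With the term for library sets it was 3785, within the first set alone 63 and within the second alone 2914.

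**Figure D1:**
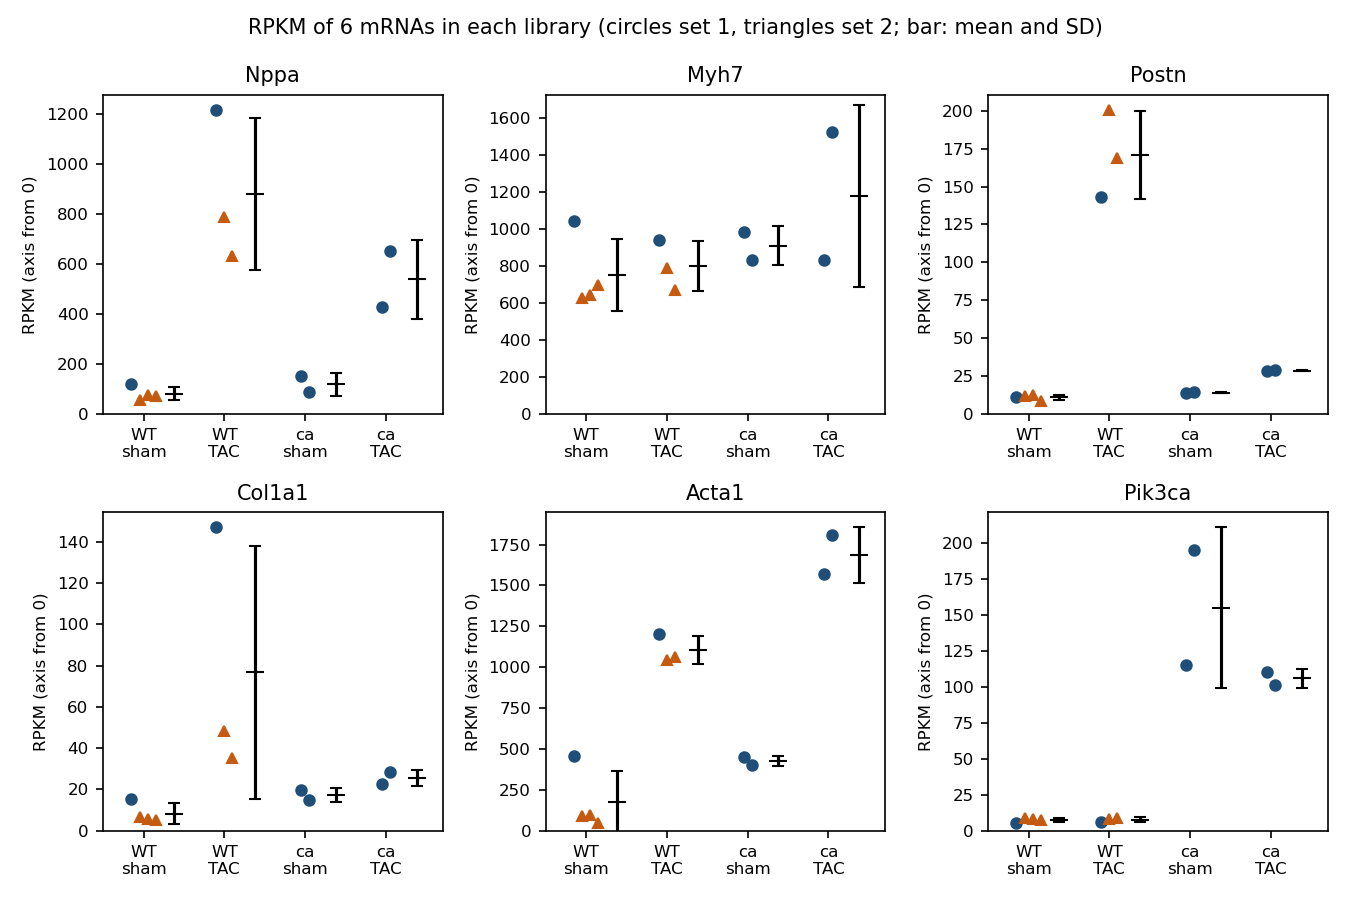
RPKM of 6 genes in each mRNA library, by group, with circles for libraries of the first set and triangles for the second, and the bar beside each group is its mean with 1 SD. Postn stands at 171 RPKM in WT TAC and at 28.4 RPKM in caPI3Kalpha TAC, and Pik3ca at 7.12 in WT sham and 155 in caPI3Kalpha sham.

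The miRNAs of the same comparison, in 4 WT sham and 5 WT TAC hearts, showed miR-21 going from 4240.2 ± 758 to 14329.8 ± 4049 CPM (counts scaled to library size), a log2 change of 1.76 (SE 0.24, adjusted p = 0.000117); it is known to rise in fibrotic and overloaded hearts. MiR-146b, described to respond to inflammatory signals, rose 3.81-fold (log2 1.93, SE 0.18) and miR-208b, encoded within Myh7, 3.06-fold (log2 1.61, SE 0.38). MiR-34b-3p rose 6.32-fold, and 11.5-fold within the second set, from 9 reads in WT sham to 97 in WT TAC (ratio 6.62, 95% counting interval 3.35 to 14.9), and miR-298 rose 4.26-fold. MiR-133a, abundant in muscle, fell by 0.44 on the log2 scale (SE 0.11).

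Of 26 miRNAs from the imprinted cluster on chromosome 12, a group made from a maternally expressed locus, 15 rose and none fell in edgeR, 21 adjusted over the list alone, with a median of 1.12 (adjusted p = 0.000394 with an estimated correlation); miR-410 rose by 1.24, miR-127 by 1.07 and miR-541 by 1.42. For miR-668 of this cluster 2 reads were counted in WT sham and 47 in WT TAC, a ratio of 14.4 (95% counting interval 3.78 to 123); its 12.1-fold rise in edgeR was 76.0-fold without WT sham 13, and within the second set alone it was 6.11-fold and did not pass. Of 19 miRNAs described to rise in pressure overload 8 rose, 10 adjusted over the list alone (adjusted p = 0.113 with an estimated correlation), miR-34c (1.55), miR-214 (1.12) and miR-222 (0.56) among them. In the miR-29 and miR-30 families, of which miR-29 is described to target collagens, 4 of 8 members fell, 6 adjusted over the list alone (adjusted p = 0.241 with an estimated correlation): miR-30e (-0.61), miR-30d (-0.52), miR-30c (-0.45) and miR-30a (-0.39). MiR-29a stood at -0.47 (SE 0.20, adjusted p = 0.115), and miR-1, miR-499 and miR-208a-3p at -0.50, -0.59 and -0.40 did not pass. Other falls were miR-338-5p (-0.99), miR-101a (-0.76), miR-192 (-0.59), miR-582-5p (-0.58) and miR-181c (-0.58). In total 34 miRNAs rose and 19 fell of 262 tested. By library totals without TMM scaling 57 rose and 3 fell, with the median of all miRNAs at 0.27 in place of -0.04, and the falls of miR-133a (-0.13), miR-338-5p, miR-582-5p and the 4 miR-30 members named here no longer passed. With the set term 48 rose and 53 fell. Without WT sham 6 the count was 28, without WT sham 7 it was 26 and without WT TAC 20 it was 35.

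The next comparison asks what the transgene does without load. Pik3ca, which encodes the expressed subunit, stood at 155 ± 56.3 RPKM (SD, n = 2) in caPI3Kalpha sham and 7.12 ± 1.36 (SD, n = 4) in WT sham, a log2 change of 4.32 (SE 0.24, adjusted p = 1.85e-05), and was the 1 gene past the threshold in limma; 1193 genes had an unadjusted p under 0.05. Among genes of the stressed heart that did not pass, Acta1 stood at 1.87 (SE 0.63, adjusted p = 0.326), with the set term at 0.76, within the first set at -0.10 and without WT sham 6 at 2.52, which passed. Nppa stood at 0.57 (SE 0.34), Col1a1 at 1.14 (SE 0.53) and Myh6 at -0.05 (SE 0.15); with the set term they stood at -0.03, -0.04 and -0.28.

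As groups, the extracellular matrix list lay higher in caPI3Kalpha sham (median 0.35, camera, adjusted p = 5.08e-05, and 0.659 with an estimated correlation). So did the hypertrophic marker genes (median 0.34, camera, adjusted p = 0.00459, and 0.659 with an estimated correlation). No member of either list passed the threshold over all genes or adjusted over the list alone. Only 1 of the 4 WT sham libraries shares a set with the caPI3Kalpha libraries, so set and transgene are partly mixed in these list values. With the set term camera called 8 mRNA lists in place of 2. In limma without WT sham 6, the 1 WT sham library of the set that holds the caPI3Kalpha libraries, 1824 genes passed, and within that set alone none did (115 at an unadjusted p under 0.05). None of 262 miRNAs passed in edgeR, with 4 at an unadjusted p under 0.05, and none in DESeq2, with 6. MiR-21 stood at 0.24 (SE 0.26) and miR-208b at 0.13 (SE 0.42; -0.12 with the set term and -0.89 within the second set). The blood cell miRNAs lay lower as a list (median -0.20, adjusted p = 0.0365; adjusted p = 0.0913 with an estimated correlation).

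In caPI3Kalpha hearts the comparison of 2 TAC with 2 sham mRNA libraries asks what load does under raised PI3K activity. Nppa stood at 539 ± 159 RPKM after TAC and 118 ± 46.2 after sham (SD, n = 2 each; log2 2.21, SE 0.39, adjusted p = 0.130). Cilp, a matrix gene of activated fibroblasts, stood at 1.96 (SE 0.36), Postn at 1.01 (SE 0.20) and Ankrd1 at 1.45 (SE 0.28). No gene passed over all 8987 in limma, and 454 had an unadjusted p under 0.05. With the set term 58 genes rose and 35 fell, including Nppa at 2.21 (adjusted p = 0.00520) and Atp2a2 at -0.45 (adjusted p = 0.00889). Within the first set alone, which holds all 4 of these libraries, and in a fit of the 2 groups alone 0 passed by limma, with 1152 and 1145 at an unadjusted p under 0.05, so that the calls of the set term were not found without the WT libraries of the second set. Without WT sham 6 in the planned design 2 passed.

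Adjusted over the list alone, 15 of 39 extracellular matrix genes and 6 of 12 hypertrophic markers rose, none of them past the threshold over all genes. The matrix list had a median of 0.55 (camera, adjusted p = 6.89e-20; adjusted p = 0.0936 with an estimated correlation) and the hypertrophic list 0.79 (adjusted p = 5.68e-10; adjusted p = 0.0520 with an estimated correlation). The ion channel list lay lower (median -0.28; adjusted p = 0.0460 with an estimated correlation), with Kcnq1, a potassium channel of repolarization, at -0.71 (SE 0.19) and no member past either adjustment. Citric acid cycle and respiratory chain lists had medians of -0.15 and -0.14 (adjusted p = 0.107 with an estimated correlation for the first and 0.0888 for the second). The immediate early genes had a median of 0.58 (adjusted p = 0.190 with an estimated correlation), with 3 of 9 past adjustment over the list alone. Macrophage markers had a median of -0.03 and 0 of 11 passed either adjustment in limma. Atrial genes lay higher as a list (median 1.39; adjusted p = 0.205 with an estimated correlation), and this was carried by 1 library: Myl7 read 20.8 RPKM in caPI3Kalpha TAC 11 and 0.4 in caPI3Kalpha TAC 211. Hba-a1, a globin gene of red blood cells, read 314 RPKM in the same library and 12.5 in the other.

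Among miRNAs, in 3 sham and 4 TAC hearts, miR-208b rose 5.29-fold (log2 2.40, SE 0.45, adjusted p = 0.00664), miR-184 3.30-fold and miR-146a 2.07-fold. MiR-673-5p (1.47), miR-34c (0.98) and miR-130b (0.88) rose also. MiR-9 fell from 56.6 ± 20.2 to 16.4 ± 4.40 CPM (log2 -1.78, SE 0.27), and miR-1195 (-2.59), miR-10a (-1.39), miR-107 (-0.78) and miR-218 (-0.77) fell. Without caPI3Kalpha sham 8 miR-1195 stood at -1.42 and no longer passed, and without caPI3Kalpha sham 5 miR-184 stood at 2.31 and miR-673-5p at 2.18. Within the second set alone miR-673-5p stood at 4.05, miR-208b at 3.11 and miR-1195 at -1.60, the last of which did not pass. MiR-133a fell by 0.60 and miR-208a-3p by 0.64 on the log2 scale. MiR-21 stood at 0.05 (SE 0.26, adjusted p = 0.922).

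Of the 8 members of the miR-29 and miR-30 families 3 fell, 3 adjusted over the list alone (adjusted p = 0.247 with an estimated correlation): miR-30b (-0.74), miR-30c (-0.61) and miR-30e (-0.68). Of the 26 chromosome 12 cluster miRNAs 3 rose, 3 adjusted over the list alone (adjusted p = 0.163 with an estimated correlation), with miR-127 at 0.81; miR-382 had no read in the 3 sham libraries and 27 in the TAC libraries, at least 5.63-fold higher against a floor of 3 counts over the group, and the median of the cluster, 0.28, was the same with miR-382 at that bound. Of the miRNAs described to rise in pressure overload 3 of 19 rose (5 by library totals without TMM), 5 adjusted over the list alone (adjusted p = 0.247 with an estimated correlation). In all 12 rose and 16 fell in edgeR, while a fit of these 2 groups alone called 0 (55 at an unadjusted p under 0.05) and the set term 26 and 42. By library totals without TMM 22 rose and 8 fell, and the falls of miR-30e, miR-208a-3p and miR-218 no longer passed. Within each library set 18 passed. Leaving out WT sham 6 gave 17, WT TAC 2 gave 18, WT TAC 17 gave 17, WT TAC 20 gave 16, caPI3Kalpha sham 5 gave 11, caPI3Kalpha sham 8 gave 18, caPI3Kalpha TAC 8 gave 17, caPI3Kalpha TAC 9 gave 6 and caPI3Kalpha TAC 11 gave 10.

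**Figure D2:**
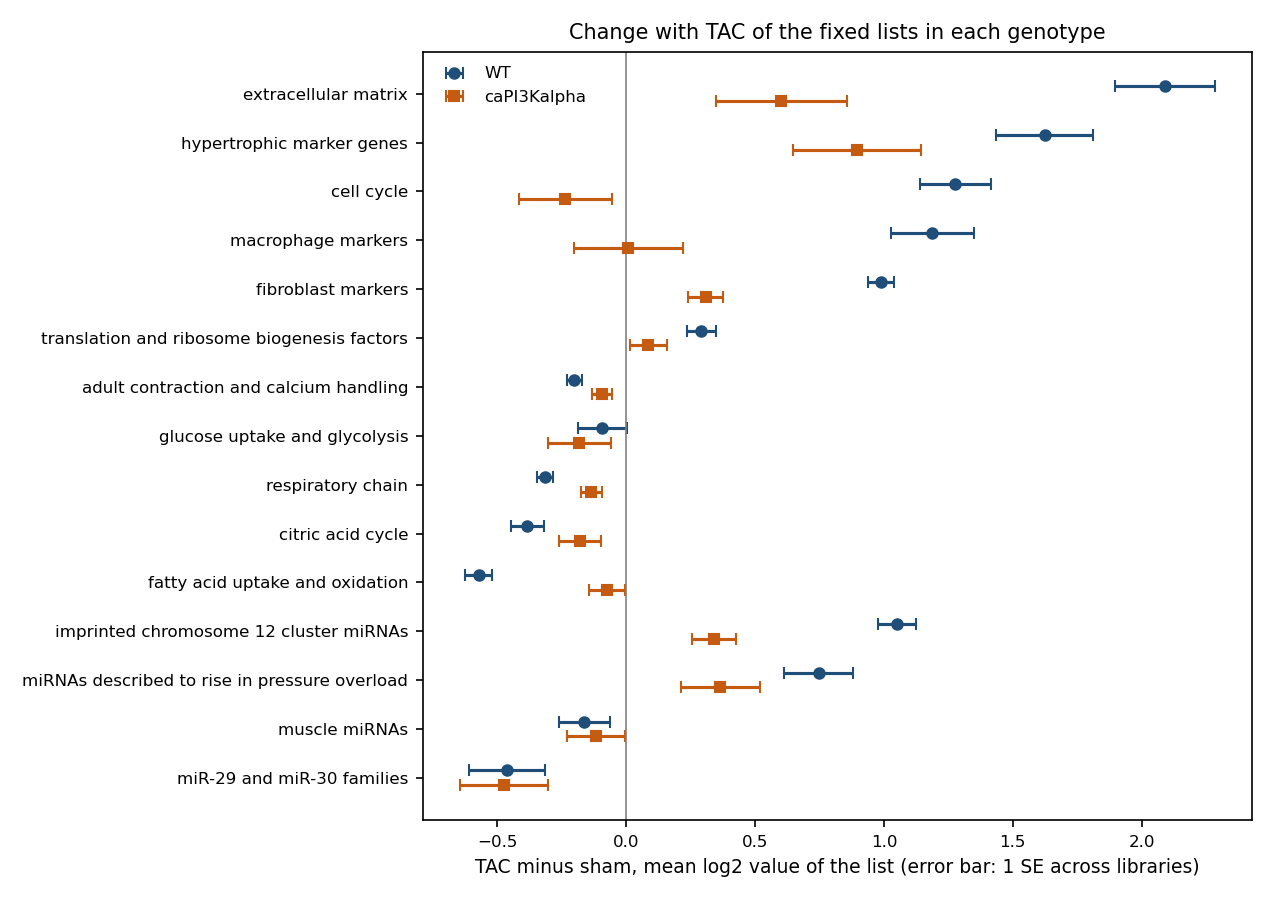
Change with TAC of the mean log2 value of 15 fixed lists, in WT (circles) and caPI3Kalpha (squares), with bars of 1 SE across libraries, RPKM for mRNA and CPM for miRNA. The extracellular matrix list changed by 2.09 in WT and 0.60 in caPI3Kalpha, and the miR-29 and miR-30 list by -0.46 and -0.47.

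Whether load acts differently in the 2 genotypes was tested as the interaction, the TAC effect in caPI3Kalpha minus that in WT. Postn had a smaller rise in caPI3Kalpha by 2.91 on the log2 scale (-2.91, SE 0.25, adjusted p = 0.00105), as had Fn1, the fibronectin gene (-2.45, SE 0.40), and Col3a1, the type III collagen gene (-2.31, SE 0.40). Ccl8 (-3.39), S100a4, a marker of activated fibroblasts (-2.86), and Aldh1a2, which makes retinoic acid (-2.77), showed the same direction; with a pseudocount of 0.1 Ccl8 stood at -3.98 and Aldh1a2 at -3.49, and within the first set Fn1 stood at -3.11 and did not pass. In all 28 genes passed, 28 of them negative and 28 of them among those that rose in WT TAC. The interaction and the WT comparison share the WT libraries, so this overlap is not separate evidence of a smaller response. The median over all genes was -0.16, and with centring on library medians 12 genes passed, 12 negative, and with quantile normalization 18, of which 15 were negative.

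Of 39 extracellular matrix genes 9 were called negative, 28 adjusted over the list alone, and all 39 estimates were below 0 in the planned design, with a median of -1.31 (adjusted p = 0.0430 with an estimated correlation); Col5a2 (-1.97), Bgn (-1.41) and Col8a1 (-1.63) were among them, and Col1a1 stood at -2.44 (SE 0.77, adjusted p = 0.269; -1.83 without WT TAC 1). The matrix genes called numbered 5 with quantile normalization and 4 centred on library medians. Fibroblast and macrophage markers moved the same way: Mfap5 (-1.52) was the 1 fibroblast marker of 9 to pass, 2 adjusted over the list alone (adjusted p = 0.0430 with an estimated correlation), and 10 of 11 macrophage markers passed adjusted over the list alone and none over all genes in limma (median -1.24; adjusted p = 0.0442 with an estimated correlation). Of 8 cell cycle genes 7 passed adjusted over the list alone and none over all genes, Mki67 at -2.66 (SE 0.56; adjusted p = 0.0286 with an estimated correlation). The fatty acid list lay higher (median 0.46; adjusted p = 0.0160 with an estimated correlation), 4 of 28 adjusted over the list alone and none over all genes, with Ucp3 at 1.82 (SE 0.35) and Acaa2 at 0.57 (SE 0.17). Nppa stood at -1.26 (SE 0.50, adjusted p = 0.382), Acta1 at -1.26 (SE 0.92) and Atp2a2 at 0.04 (SE 0.14). Acta1 turned to 0.58 within the first set alone and stood at -1.91 without WT sham 6, which passed.

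The count of 28 was 607 with the set term (75 positive, 532 negative), which kept all 28, and 0 within the first set alone by limma, with 1110 at an unadjusted p under 0.05. Leaving out WT sham 6, 7, 13 or 15 gave 66, 13, 17 and 15 genes, WT TAC 17 gave 4, caPI3Kalpha sham 5 and 8 gave 5 and 12, and caPI3Kalpha TAC 11 and 211 gave 3 and 4.

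Among miRNAs the interaction was negative for miR-21 (-1.71, SE 0.34, adjusted p = 0.0216) and miR-146b (-1.29, SE 0.26, adjusted p = 0.0216), 2 of 262. The chromosome 12 cluster lay lower as a list (median -0.81; adjusted p = 0.0112 with an estimated correlation), 9 of 26 adjusted over the list alone and none over all miRNAs in edgeR (2 by library totals without TMM), with miR-410 at -0.96 (SE 0.23). MiR-208b stood at 0.79 (SE 0.56, adjusted p = 0.666) and the miR-29 and miR-30 list at a median of 0.03 (adjusted p = 0.630). The set term called 14 and DESeq2 5. Without WT sham 15 the edgeR count was 5, without caPI3Kalpha sham 14 it was 3, without WT sham 6 it stayed 2, and it was 0 without any 1 of the other 13 libraries.

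The 2 TAC groups were also set side by side. Ccl8 was lower in caPI3Kalpha TAC by 2.82 on the log2 scale (-2.82, SE 0.24, adjusted p = 0.000296), Spp1 by 3.37 (-3.37; -4.39 and -2.73 with pseudocounts of 0.1 and 1) and Postn by 2.55 (-2.55), in 2 caPI3Kalpha and 3 WT libraries. Timp1 (-2.78; -3.52 with the set term), Hp, which encodes haptoglobin (-2.71; -3.63 with the set term, and -3.85 with a pseudocount of 0.1, where it no longer passed), and Tnc, which encodes tenascin C (-2.58; -3.37 with that pseudocount), were lower too; within the first set alone Spp1 (-4.45), Timp1 (-3.64) and Hp (-3.67) did not pass. Pik3ca (3.75), Enho, which encodes the peptide adropin (1.79; 1.13 within the first set alone, where it did not pass), Rasd1 (1.66), Thrsp, known from the control of lipid synthesis (1.65), Slc25a34 (1.34) and Ucp3 (1.28) were higher. Of the matrix list 18 of 39 were lower, 23 adjusted over the list alone (adjusted p = 0.219 with an estimated correlation); of the macrophage markers 7 of 11, 8 adjusted over the list alone (adjusted p = 0.196 with an estimated correlation); and of the cell cycle genes 7 of 8 (4 centred on library medians), 8 adjusted over the list alone (adjusted p = 0.147 with an estimated correlation). Of the fatty acid list 9 of 28 were higher, Fabp3 (0.76) and Mlycd (0.97) among them; adjusted over the list alone 15 were higher and 2 lower (adjusted p = 0.144 with an estimated correlation). In the PI3K, insulin and mTOR list Igf1 (-1.68), Irs1 (-0.93) and Igf1r (-0.67) were lower beside Pik3ca; in all 1 of 26 was higher and 4 lower (2 lower with quantile normalization or centring), and adjusted over the list alone 3 and 7. Nppa stood at -0.68 (SE 0.36) and Acta1 at 0.61 (SE 0.67; -0.37 with the set term).

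Of 8987 genes 67 were higher and 519 lower. The caPI3Kalpha TAC libraries all lie in the first set and 2 of 3 WT TAC libraries in the second, so genotype and set are partly mixed here. With the set term 113 were higher and 696 lower, and 482 of the 586 calls were kept. Centred on library medians 130 were higher and 139 lower, with quantile normalization 72 and 143, and the median over all genes was -0.18. A fit of these 2 groups alone called 8 and 71, and within the first set, which holds 1 WT TAC library, 1 gene passed. Each of the 11 libraries, left out in turn, moved the count of 586 by more than 1.5 times, from 23 without caPI3Kalpha TAC 11 to 3269 without WT TAC 1.

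MiR-21 was lower in caPI3Kalpha TAC by 1.47 on the log2 scale (-1.47, SE 0.23, adjusted p = 0.00302; 4 and 5 libraries) and miR-146b by 0.99 (-0.99, SE 0.18). MiR-540-3p (-1.75), miR-341 (-1.31), miR-299 (-1.02) and miR-409-3p (-0.99) were lower, and miR-153 (1.30), miR-141 (0.90), miR-146a (0.88), miR-181d (0.59), miR-488 (0.54) and miR-192 (0.47) higher. Of 26 chromosome 12 cluster miRNAs 10 were lower, 14 adjusted over the list alone (adjusted p = 0.00413 with an estimated correlation). MiR-144, a miRNA of red blood cells, was higher by 2.96 (SE 0.89; 3.56 without WT TAC 1; 2.31 within the first set alone, where it did not pass), and its partner miR-451 read between 1313 and 1944 CPM in caPI3Kalpha TAC 8, 9 and 11 and 52.9 in caPI3Kalpha TAC 211. In all 11 miRNAs were higher and 23 lower; by library totals without TMM 7 and 41, with the set term 23 and 41, and within the second set alone 5 and 8. Leaving out WT TAC 1, 2, 17 or 20 gave 22, 18, 15 and 15, and caPI3Kalpha TAC 8, 9, 11 or 211 gave 18, 18, 15 and 21.

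**Figure D3:**
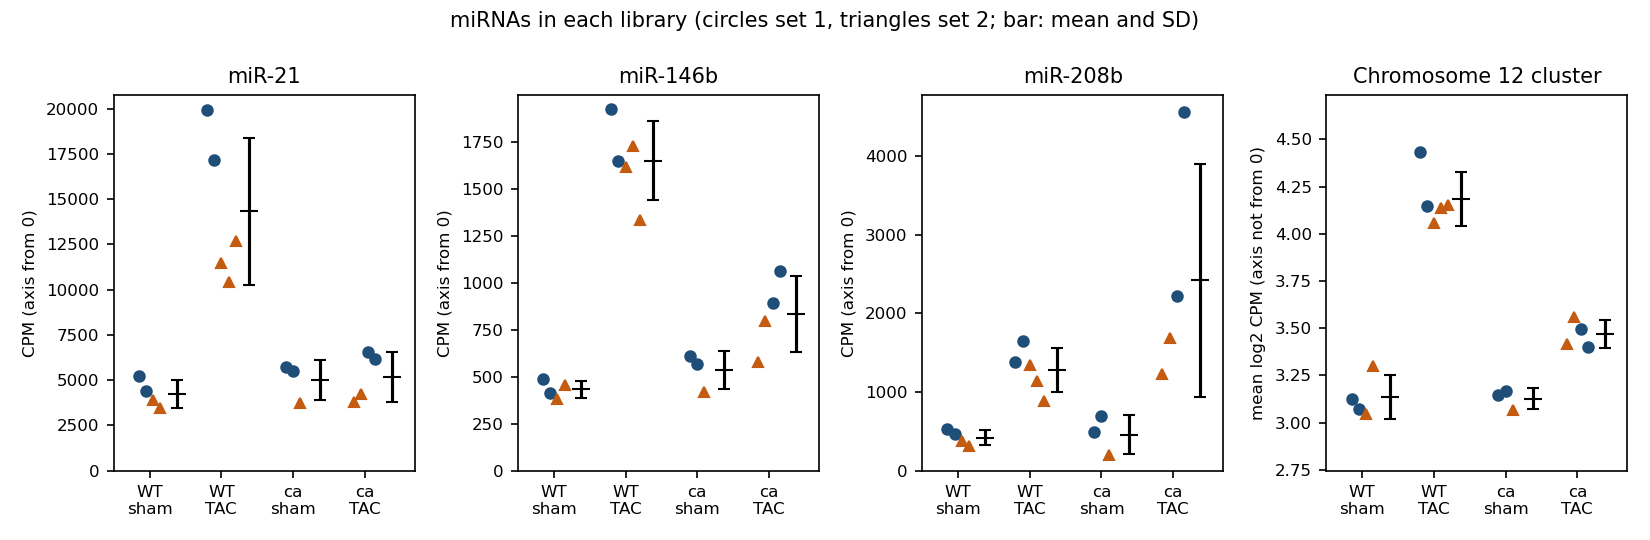
CPM of miR-21, miR-146b and miR-208b in each miRNA library, and the mean log2 CPM of the 26 chromosome 12 cluster miRNAs, by group, with circles for the first set and triangles for the second, and bars that show the mean with 1 SD. MiR-21 stands at 14329.8 CPM in WT TAC and 5171 in caPI3Kalpha TAC.

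The responses of the 2 genotypes were compared across genes. The log2 changes with TAC had a Pearson r of 0.44 and a Spearman rho of 0.38 over 8987 genes, and of 0.43 and 0.53 over 262 miRNAs; these are correlations across genes, which are not independent replicates, and the 2 genotypes share no library. With the set term, 55 genes rose in both genotypes where chance gives 19.2, and 26 fell in both where chance gives 3.15. In the planned fit 0 genes passed in caPI3Kalpha, so no overlap could be counted. Among miRNAs 8 rose and 6 fell in both, miR-208b, miR-34c and miR-214 among the former and miR-30c and miR-30e among the latter, where chance gives 1.56 and 1.16. The calls of both genotypes used the same spread per feature from 1 fit. They are thus not independent, and the overlap by chance may be higher than these values.

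In the 11 hearts with both measurements, 17 pairs of a miRNA with its host gene or a described target were correlated. Myh6 and miR-208a-3p, which lies in an intron of Myh6, had r = 0.73 (permutation p = 0.0095, adjusted p = 0.161) and rho = 0.68 (permutation p = 0.0244), with r = 0.70 after the 2 hearts farthest from the median were left out and r = 0.83 within the first mRNA set (n = 6, exact p = 0.0528). In residuals from the group means its r was 0.37 (permutation p = 0.263), and the other arm, miR-208a-5p, had r = 0.20 with Myh6 and -0.17 without 2 hearts. Myh7 and miR-208b had r = 0.62 (permutation p = 0.0397, adjusted p = 0.274) and rho = 0.52 (permutation p = 0.107), r = 0.24 without 2 hearts, r = 0.69 in residuals and r = 0.52 within the set (exact p = 0.289). Fbn1, the fibrillin gene, and miR-29c, described to target it, had r = -0.58 (permutation p = 0.0633, adjusted p = 0.274) and rho = -0.36 (permutation p = 0.271), r = -0.20 without 2 hearts and r = -0.90 within the set (exact p = 0.0236, adjusted p = 0.15). In residuals from the group means its r was 0.42, and 0.12 with the sets removed as well, and all 9 pairs of a miR-29 with a described target had a positive r in both. Over the 11 hearts, without residuals, none of the 17 pairs passed in two-sided permutation tests, and 2 had an unadjusted p under 0.05. In residuals from the group means 3 pairs passed. Ppargc1b with miR-378, a host gene pair, had a negative r of -0.80 (adjusted permutation p = 0.0326), against 0.79 within the first mRNA set. The others were Col1a1 and Col3a1 with miR-29b, with r = 0.74 and 0.87. In residuals from group means and library sets 1 pair passed, Col3a1 with miR-29b, with a positive r of 0.84 (adjusted permutation p = 0.0282). These permutations treated the 11 residuals as independent hearts though group means had been removed. Their p values are therefore too small, and the counts of pairs show no link. Within the first mRNA set, 6 hearts, none passed an exact test.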

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

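The tests of the 3 patterns weighed here and the splits within library sets were chosen after the result was seen, and the counts of splits across all libraries were planned.

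Of 43 groups of 4 or 5 hearts checked, 2 held a heart far from the others, where chance gives about 1 in 20. Acta1 read 455.2 RPKM in WT sham 6 and 47.4 to 93.7 in the other 3 WT sham hearts; WT sham 6 is the 1 WT sham library of the first mRNA set, and the 2 caPI3Kalpha sham libraries of that set read 448.3 and 403.8. MiR-451 read 507 CPM in WT TAC 1 and 88.3 to 182 in the other 4 WT TAC hearts.

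For 12 named features the TAC effect differed between genotypes in the test of the interaction, by limma for mRNA and edgeR for miRNA. On the log2 scale the difference was -3.39 for Ccl8, -2.91 for Postn, -2.86 for S100a4, -2.77 for Aldh1a2, -2.45 for Fn1, -2.31 for Col3a1, -1.97 for Col5a2, -1.63 for Col8a1, -1.52 for Mfap5 and -1.41 for Bgn. It was -1.71 for miR-21 and -1.29 for miR-146b. Adjusted p ran from 0.00105 for Postn to 0.0455 for Col3a1. Of the fibroblast markers, Dcn read 267, 366, 191 and 241 RPKM and Mfap5 3.45, 21.8, 5.75 and 11.8 in WT sham, WT TAC, caPI3Kalpha sham and caPI3Kalpha TAC, in whole ventricle with no sort of cells described.

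The first pattern is the smaller rise of the extracellular matrix list with TAC in caPI3Kalpha (0.60, SE 0.25) than in WT (2.09, SE 0.19). A difference between library sets as its whole cause is argued against by 2 fits, each under an assumption. With the set term over all 11 libraries the interaction of the list's mean was -1.45 (SE 0.21). No caPI3Kalpha mRNA library lies in the second set, so that fit assumes the same TAC effect in WT in both sets. In the first set alone the interaction was -1.60 (SE 0.337, 95% interval -3.05 to -0.15). There the 1 WT sham and 1 WT TAC heart show no spread. They were assumed to vary like the 2 caPI3Kalpha sham and 2 caPI3Kalpha TAC hearts. Fewer added fibroblasts in caPI3Kalpha TAC were not settled as a cause. The matrix list kept 0.288 (SE 0.124) of its WT change and 7 fibroblast markers outside it kept 0.281 (SE 0.113). The difference of 0.00753 (SE 0.168) cannot decide, since a response damped in the same proportion in all these genes also gives equal shares. A first form of this test, the difference of the log2 interactions, gave -0.78 (SE 0.197). It was dropped after it was run because the list rises more than the markers in WT. A lower number of added fibroblasts shifts list and markers by the same log2 amount only if added and resident cells express these genes alike. Expression per cell was not measured, so the first form cannot decide either. A weaker response to pressure throughout cannot be told apart in the planned design. There the miR-29 and miR-30 list lay -0.34 (SE 0.183) from the value it predicts, under 2 SE. With the set term the distance was -0.29 (SE 0.0854), over 2 SE, which goes against it for this list. The 2 fits differ, and the falls of the miR-30 members in WT no longer passed without TMM. The question is left undecided. An effect of the genotype stays open too: the interaction tests that the responses differ, and no test here shows the genotype to be the cause.

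The second pattern is the rise of the chromosome 12 cluster miRNAs in WT TAC. TMM scaling lowered these changes: by library totals without it the lower quartile of the members' log2 changes was 1.18 and their median 1.43. The TMM factors were higher in WT TAC than in WT sham, so leaving them out had to raise the change of each miRNA. The values give the direction of the scaling's effect and are not a separate test. A difference between library sets is argued against by a change of the list's mean of 0.94 (SE 0.0998) in 1 set and 1.19 in the other. A higher level of the cluster's long RNA may account for it. Meg3, a long noncoding RNA of the cluster, followed the list's mean across 11 hearts (r = 0.774, permutation p = 0.00351, and rho = 0.591, permutation p = 0.0617). Its r was 0.551 without the 2 farthest hearts, 0.339 in residuals from the group means and 0.831 within the first mRNA set (n = 6). Meg3 and the cluster were both higher in WT TAC, so r across hearts in part restates the group difference. In caPI3Kalpha the cluster's score rose with TAC while Meg3 showed no rise, as given below. An effect of TAC stays open too: the comparison tests that the groups differ, and no test here shows the operation to be the cause.

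The third pattern is the conflict in the labels of the mRNA library titled WT sham 15. An exchange of the mRNA libraries WT sham 13 and 15 is argued against by red blood cell RNA: Hba-a1 mRNA followed miR-451 across the 11 hearts as titled (r = 0.875, permutation p = 0.00132; rho = 0.791; r = 0.893 without 2 hearts), and with the libraries exchanged r was 0.588. The farther of the 2 hearts lay 0.678 residual SD from the line through the other 9 as titled and 3.03 when exchanged. WT sham 7, whose 2 libraries also lie in different sets, is off this line (681 CPM of miR-451 with 14.6 RPKM of Hba-a1, 3.74 residual SD from a line fitted without it), and with that line the distances are 1.22 as titled and 5.44 exchanged. A wrong number with no partner among these hearts, or one that involves WT sham 7, stays open, untested.

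Other splits of the same libraries into groups of the same sizes were counted. For mRNA in WT TAC with WT sham, 1 of 35 splits, the real one, gave as many genes (1481, highest other 790). That is a share under 0.05 with libraries exchanged freely, which ignores the library sets. The same holds for miRNAs in WT TAC with WT sham (1 of 100; 53, highest other 27, in a split that parts the 2 library sets), in caPI3Kalpha TAC with caPI3Kalpha sham (1 of 35; 28, highest other 3) and between the TAC groups (1 of 100; 34, highest other 15). For caPI3Kalpha sham with WT sham the real count was 0, which each split must reach (35 of 35, highest other 2), so that the count says nothing about chance. For the miRNA interaction 3 of 100 splits gave as many (2, highest other 41). The share is under 0.05, but with a real count of 2 and 41 in another split chance is not excluded. These splits exchange genotypes within an operation, so they do not test the interaction apart from other differences between genotypes. A split with many times the real count points to structure among the libraries. That split keeps sham with sham and TAC with TAC and follows the miRNA library sets in part: its caPI3Kalpha sham group is WT sham 6 and caPI3Kalpha sham 5 and 8, all of the first set, and its caPI3Kalpha TAC group is WT TAC 17, 19 and 20 and caPI3Kalpha TAC 9, all of the second. Its other groups are mixed, 3 of 4 libraries of the second set and 4 of 5 of the first. With the set term the count was 14, and within the 2 sets 1 and 0. With libraries exchanged only within their set, 1 of 60 splits gave as many miRNAs in WT TAC with WT sham (highest other 12) and 1 of 60 between the TAC groups (highest other 15), and 4 of 100 for the interaction (highest other 4). The 20 such splits of the mRNA libraries in WT (highest other 0) and the 18 of the miRNA libraries in caPI3Kalpha (highest other 2) are too few for a share under 0.05. Chance is therefore not excluded for these 2 results when the sets are kept.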

How the results depend on the processing

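The set term, the fits within each set, the totals without TMM and the residuals from group means and sets were chosen after the data were seen. No paired analysis was possible because each animal had 1 operation and the labels give no litters. Of 6031 alternative values of 278 named results, 4956 kept their side of the threshold, 1043 no longer passed, 32 newly passed and 0 that passed reversed. Among the 4956, 89 that passed in neither fit changed sign. For counts that moved more than 1.5 times the cause was not tested, except that fits of 2 groups or 1 set hold fewer libraries.

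Quantile normalization gave 925 mRNAs for WT TAC with WT sham, 18 for the interaction and 215 between the TAC groups, and centring on medians 12 for the interaction and 269 between the TAC groups. Fits of 2 groups gave 890 mRNAs in WT, 79 between the TAC groups, and 0 miRNAs (55 at an unadjusted p under 0.05) in caPI3Kalpha by edgeR. With no filter 34 miRNAs passed in WT. DESeq2 gave 5 miRNAs for the interaction and totals without TMM 4.

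The set term gave 3785 mRNAs in WT, 93 in caPI3Kalpha and 607 for the interaction, and 101, 68, 14 and 64 miRNAs in WT, in caPI3Kalpha, for the interaction and between the TAC groups. Set 1 alone gave by limma 63 mRNAs in WT, 0 for caPI3Kalpha sham with WT sham (115 at an unadjusted p under 0.05), 0 in caPI3Kalpha (1152), 0 for the interaction (1110) and 1 between the TAC groups, and 18 miRNAs in caPI3Kalpha and 1 for the interaction. Set 2 alone gave 2914 mRNAs in WT, and by edgeR 18 miRNAs in caPI3Kalpha, 0 for the interaction (36 at an unadjusted p under 0.05) and 13 between the TAC groups.

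With an estimated correlation camera called 0 mRNA lists for caPI3Kalpha sham with WT sham (2 as planned), 1 in caPI3Kalpha (10) and 0 between the TAC groups (13), and 1 miRNA list in WT (3), 0 for caPI3Kalpha sham with WT sham (1) and 0 in caPI3Kalpha (3). The set term gave 8 mRNA lists for caPI3Kalpha sham with WT sham. Correlation of the 2 genotypes' TAC responses over features called in either was 0.578 for mRNA and 0.627 for miRNA. Of the pairs 3 passed in residuals from group means and 1 in residuals from group means and sets. Those permutations treated residuals as independent hearts, so their p values are too small.

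Leaving out each library in turn gave 729 to 1994 mRNAs in WT, 1 to 1824 for caPI3Kalpha sham with WT sham (1824 without WT sham 6), 0 to 2 in caPI3Kalpha, 3 to 66 for the interaction and 23 to 3269 between the TAC groups. For miRNAs it gave 26 to 58, 0 to 0, 6 to 24, 0 to 5 and 15 to 38 in that order. Lists called were 12 to 13, 1 to 6, 9 to 13, 10 to 12 and 8 to 14 for mRNA and 3 to 3, 0 to 1, 3 to 4, 1 to 3 and 1 to 2 for miRNA. A lone library left in a group was assumed to vary like the other groups. Pseudocounts of 0.5 and 10 and median centring for miRNA were not run, since they apply to normalized values, and no filter for mRNA removed no gene. Depth of the mRNA libraries is unknown, so its limits were not assessed.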

Other observations

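The tests of Meg3 and the list scores of other cell types were chosen after the data were seen. Meg3, which gives rise to a long RNA from the same imprinted region as the chromosome 12 miRNAs, rose in WT TAC by 1.32 on the log2 scale (SE 0.31, adjusted p = 0.0150). In caPI3Kalpha it stood at -0.26 (SE 0.40), with an interaction of -1.58 (SE 0.50, adjusted p = 0.279). The score of the cluster's miRNAs changed by 1.05 (SE 0.07) in WT and 0.34 (SE 0.08) in caPI3Kalpha. The macrophage score changed by 1.19 (SE 0.16) in WT and 0.01 (SE 0.21) in caPI3Kalpha.

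Several of the fixed lists showed little. In WT TAC with WT sham 2 of 12 apoptosis genes, 2 of 12 angiogenic factors and receptors, 3 of 16 translation factors and 1 of 10 endothelial markers rose, none of them fell, and camera called none of the 4 lists. With quantile normalization 0, 1, 0 and 0 rose and 1 of the angiogenic genes fell. Of 9 let-7 miRNAs and 9 miRNAs of the miR-17 to miR-92 cluster and its copies 0 passed in edgeR. Red blood cell RNA varied within groups: Hba-a1 read 82.6, 14.6, 80.2 and 6 RPKM in WT sham 6, 7, 13 and 15, and 4.9 and 105 in caPI3Kalpha sham 5 and 8. Pik3ca read 5.3 to 8.9 RPKM in the 7 WT libraries and 101.3 to 195.0 in the 4 caPI3Kalpha libraries, so that each library's genotype matched its label.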
